A study of Mus musculus with 11 samples.

How the data were processed

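The series holds 11 polyA RNA sequencing libraries from microdissected mouse tailbud tissue at embryonic day 8.5: 4 wild-type, 3 Fgfr1 FCPG and 4 Fgfr1 FCSPG libraries. RNA was made into libraries with a stranded mRNA kit, per the labels' protocols. The counts were made by the authors by aligning reads with HISAT2 to the mouse build mm39 and counting them per gene with featureCounts, per the submitters' processing notes. Those notes give no versions, no annotation release and no counting options, so it is not stated whether the counting used strand. Antisense and overlapping genes, and genes that share reads with near-identical copies, such as ribosomal protein genes and globins, are therefore uncertain. The deposited count table holds whole numbers for 56748 genes with names, coordinates, biotypes and lengths, which were used as given, and 882 gene symbols occur more than once. A deposited table of FPKM values covers the same genes and libraries and was not used, because counts allow a count test.

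The authors also deposited tables of log2 fold changes with a p-value and adjusted p-value per gene for the 3 comparisons, made with DESeq2 per the submitters' processing notes. Their log2 values are the first group named in the file over the second, per the file headers and the group means beside them, and were turned here to mutant over wild type and FCSPG over FCPG. The deposited tables list only genes with an unadjusted p-value under 0.05. DESeq2 fitted here to the counts of the 2 groups compared gave p-values equal within 1e-06 for 100% of the listed genes.

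Libraries were assigned to groups by the genotype in the column names, and 0 columns were left over. The column names carry other numbers than the sample titles, so no replicate number could be given to a column, and libraries are named here by their column number. The design and the first set of alternatives below were chosen before the data were examined, as were 52 gene lists written from textbook knowledge. They hold 873 symbols, of which 4 were not found in the table. The 51 lists with 5 or more tested members were tested, and the sex-linked list was used only to read embryo sex from Xist and Y-linked counts.

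The main test was edgeR 4.0.16's quasi-likelihood F test on all 11 libraries with TMM scaling and 1 term for the 3 groups, two-sided, in R 4.3.3. Genes were kept by edgeR's filterByExpr, which left 16572 genes holding at least 99.88% of each library's counts. P-values were adjusted over these genes by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold change. CPM values were computed here from the counts with TMM factors, and log2 CPM with a prior count of 2. Gene lists were tested with camera of limma 3.58.1 on the edgeR fit, with its preset inter-gene correlation of 0.01 and adjustment over 51 lists. Beside it stand camera with a correlation estimated per list, limma's fry test, which tests whether a list's genes move on balance in 1 direction, and an exact two-sided permutation of the library scores of each list. The smallest p that permutation can give is 0.0286, both for 3 against 4 libraries and for 4 against 4. In no list did the median and the camera test differ in sign where camera made a call, a count of 0 lists.

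Genes are named by a rule fixed in advance. It takes Fgfr1, then up to 6 genes per direction past the threshold with a mean of 5 CPM or more, and up to 4 members of each list with the smallest p. The threshold part gave 0 genes in each comparison, so Fgfr1 and the list members are named, and the text uses a part of them. Genes named outside the rule are said to be so. For the 2 comparisons that share the wild-type libraries, unchanged groups were simulated 20 times with edgeR and 5 times with DESeq2, and the wild-type libraries were split into pairs in 6 ways.

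The test was tried on simulated counts with the means, library sizes and gene-wise dispersions of the real libraries, with 200 of 16572 genes changed. For FCPG against wild type it recovered 27% of genes changed 2-fold and 82% of genes changed 4-fold. For FCSPG against wild type it recovered 45% and 83%, and for FCSPG against FCPG 35% and 71%. The simulated genes were drawn independently, without variation shared between libraries, so these shares need not hold in the real libraries. The fitted coefficient of variation between libraries was 0.325, which limits the precision more than the depth of 16014698 to 25453070 counts does.

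The alternatives chosen in advance were DESeq2 size factors in edgeR, DESeq2 1.42.0's Wald test, limma-voom, no filter on low counts, a filter of 1 CPM in at least 3 libraries, only the 2 groups compared, a minimum log2 fold change of 1, an estimated correlation and the fry test for lists, split wild-type libraries, and each library left out in turn. Alternatives added after the data were seen were an embryo-sex covariate, the visceral endoderm score as a covariate, the female libraries alone, which leaves FCPG with 1 library, DESeq2 on the 2 groups compared, the gene-length trend removed per library with a loess offset, the permutation of list scores, and DESeq2's counts of genes shared by both mutants, on all 3 groups and on 2 groups. All scaling alternatives moved the median log2 fold change of all genes by under 0.1 in each comparison. A block by replicate number was also chosen in advance and could not be fitted. Coordinates are those of the count table, in mm39; the reference annotation at hand is of another build and gave no coordinates.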

Results

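The data are polyA RNA sequencing libraries from tailbud tissue excised from mouse embryos at embryonic day 8.5, a stage at which the tailbud feeds new cells into the somites and the spinal cord. There were 4 wild-type libraries, 3 libraries from the Fgfr1 FCPG line and 4 from the Fgfr1 FCSPG line. In both lines, residues of the receptor FGFR1 that bind its signalling effectors carry point mutations, per the series' design. The stated purpose was to follow transcription during mesoderm development with and without canonical FGF signalling. Libraries are named by the number in the deposited column names, because those names carry no replicate number that would tie them to the sample titles. Total counts ranged from 16014698 in FCPG library 46 to 25453070 in wild-type library 26. Of 56748 genes in the table, 16572 had enough counts to be tested. Levels are given as CPM, counts scaled to library size, with the SD between libraries, and fold changes as log2 with their SE. The labels do not say whether each library came from a separate embryo, so the p-values measure only the spread between libraries.

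Fgfr1 (ENSMUSG00000031565, chromosome 8, 26003670 to 26065734, build mm39), the gene that carries the mutations, was counted in all 11 libraries. It reached 185, 169, 206 and 209 CPM in wild-type libraries 24, 25, 26 and 33. In FCPG libraries 19, 45 and 46 it reached 242, 178 and 183 CPM. In FCSPG libraries 13, 27, 30 and 32 it reached 181, 171, 162 and 248 CPM. The group means were 192 ± 18.8 CPM (SD, n = 4) in wild type, 201 ± 35.5 CPM (SD, n = 3) in FCPG and 191 ± 39.4 CPM (SD, n = 4) in FCSPG. The differences lay within the spread between libraries, and edgeR's adjusted p was 0.848 for FCPG and 0.978 for FCSPG against wild type. The alleles carry point mutations and the counts hold no sequence, so this level does not test the genotype labels.

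By correlation of log2 CPM, 7 of 11 libraries lay nearest to a library of another group, among them 3 of 3 FCPG and 3 of 4 FCSPG libraries. Wild-type library 33 was nearest to FCPG library 19 (r = 0.982 across genes, which are not independent replicates). FCSPG library 30 was nearest to wild-type library 24 (r = 0.985 across genes), FCPG libraries 45 and 46 to FCSPG library 32 (r = 0.945 and 0.965 across genes), FCSPG library 27 to wild-type library 33 (r = 0.980 across genes) and FCSPG library 32 to FCPG library 19 (r = 0.981 across genes). Genes of the visceral endoderm, the extraembryonic layer that encloses the early embryo, ran along the same axis. Their mean log2 CPM was 0.28 in wild-type library 26, 4.99 in wild-type library 33, 5.46 in FCPG library 19 and 8.73 in FCPG library 45. Y-linked transcripts reached 170 and 183 CPM in FCPG libraries 19 and 45 and 180 CPM in FCSPG library 32. They were at 0 in the other 8 libraries, whose Xist levels of 244 to 688 CPM are those of female embryos.

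**Figure D1:**
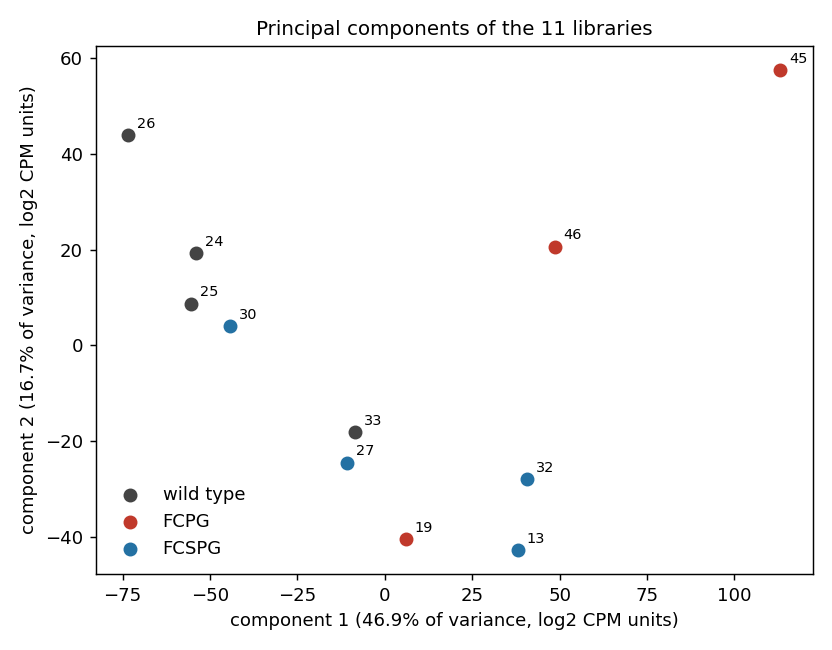
Principal components of log2 CPM in the 11 libraries, with component 1 (46.9% of the variance) on the horizontal axis and component 2 (16.7%) on the vertical axis, in log2 CPM units. Each point is a library with its number. Wild-type library 33 and FCPG library 19 follow each other in the order of component 1, at −8.44 and 5.94, but lie at −18.2 and −40.6 on component 2. FCSPG library 27, at −10.76 and −24.55, lies nearer to library 33. FCSPG library 30 lies at −44.3 on component 1, among the wild-type libraries.

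The comparison of FCPG with wild type asks how the tailbud transcriptome differs in this mutant. Visceral endoderm genes were more abundant in FCPG tailbuds, while genes of Notch signalling, of the somites, of the neural tube and of the Hox clusters were less abundant. These are calls of lists, each with adjusted p of 0.557 or more with an estimated correlation. Dab2, an endocytic adaptor of the visceral endoderm, averaged 909.8 ± 984.5 CPM (SD, n = 3) against 80.8 ± 43.6 CPM (SD, n = 4) in wild type. Nrarp, a feedback inhibitor induced by Notch, averaged 5.02 ± 2.19 CPM (SD, n = 3) against 21.3 ± 8.30 CPM (SD, n = 4), a log2 fold change of −2.08 ± 0.42 (SE). No gene passed edgeR's quasi-likelihood test after adjustment over all 16572 genes, so single genes are given as values and directions are called for gene lists.

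All 20 measured members of the visceral endoderm list were higher in FCPG, with a median log2 fold change of 3.63. The list passed limma's camera test (adjusted p = 3.44e-17), with adjusted p = 0.557 with an estimated correlation. Adjusted over the list alone, 19 members were higher. Lrp2, an endocytic receptor, averaged 273 ± 243 CPM (SD, n = 3) against 55.4 ± 11.2 CPM (SD, n = 4), and the FCPG libraries 19, 45 and 46 held 82.6, 546.5 and 191 CPM. Trf, which encodes the iron carrier transferrin, was 17.4-fold higher (log2 4.12 ± 0.89 SE) and Mttp, which loads lipid onto apolipoprotein B, 11.9-fold higher (log2 3.57 ± 0.82 SE). Each of these 3 genes was higher in 3 of 3 FCPG libraries than in every wild-type library. The definitive endoderm and hindgut list moved with them, with 15 of 18 members higher and a median log2 fold change of 1.20 (camera adjusted p = 4.71e-05). With an estimated correlation its adjusted p = 0.557. Adjusted over the list alone, 9 of its members were higher, among them the endoderm transcription factor Hnf4a (log2 4.44 ± 1.08 SE), which is also made by the visceral endoderm. With the visceral endoderm score as a covariate the definitive endoderm call ended (adjusted p = 0.999). Every FCPG library had a higher score (lowest 5.46) than every wild-type library (highest 4.99). In FCPG the fit therefore extends the trend of the score within groups across a gap between groups. A call that it ends does not show a cause.

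Genes of the segmentation clock and Notch signalling, which pace the formation of somites, were lower in 17 of 19 members, with a median log2 fold change of −1.03 (camera adjusted p = 1.72e-06). With an estimated correlation the adjusted p = 0.557. Adjusted over the list alone, 3 members were lower. Dll3, a divergent Notch ligand of the presomitic mesoderm, held 41.4, 20.7 and 2.92 CPM in FCPG libraries 19, 45 and 46 and 45.4 to 81.1 CPM in the wild-type libraries. Heyl, a Notch-induced repressor, was at 0.25 ± 0.34 CPM (SD, n = 3) against 2.62 ± 1.66 CPM (SD, n = 4). The somite and paraxial mesoderm list was lower in 14 of 16 members, with a median of −1.62 (camera adjusted p = 4.71e-05). Its adjusted p = 0.557 with an estimated correlation. Uncx, a marker of the posterior somite compartment, was at 0.32 ± 0.55 CPM (SD, n = 3) against 7.18 ± 4.61 CPM (SD, n = 4). The presomitic mesoderm list was lower in 15 of 20 members, with a median of −0.62 (camera adjusted p = 0.0117). Its adjusted p = 0.557 with an estimated correlation, and the call ended without FCPG library 45 (adjusted p = 0.0703). Within that list Mesp1, a regulator of nascent mesoderm, went the other way, at 17.1 ± 3.49 CPM (SD, n = 3) against 3.06 ± 2.72 CPM (SD, n = 4). FCPG library 45, with the highest visceral endoderm score of the 3, had a somite list score of −3.09 log2 units from the wild-type mean, library 46, between the others, had −2.97, and library 19, with the lowest, had −0.21. With that score as a covariate the somite call ended (adjusted p = 0.346, median −0.13), and the Notch median was −0.33 and the presomitic median −0.32. The score does not overlap between FCPG and wild type, so this fit does not say whether these lists follow the score or the group.

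**Figure D2:**
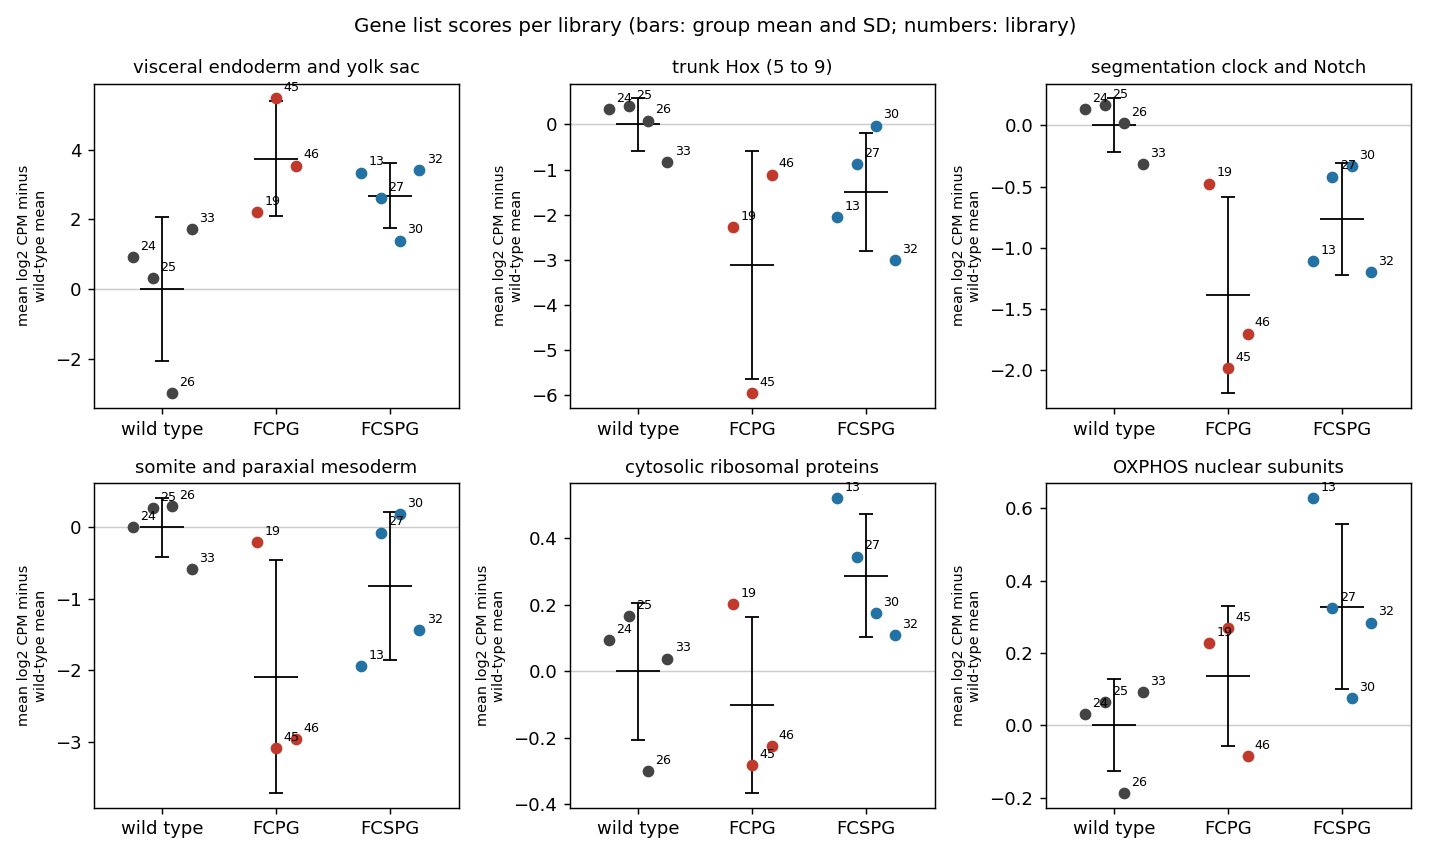
Mean log2 CPM of 6 gene lists per library, minus the wild-type mean, for wild type (n = 4), FCPG (n = 3) and FCSPG (n = 4); points are libraries with their numbers, and bars are group means with SD. Visceral endoderm scores run from −2.98 in wild-type library 26 to 5.47 in FCPG library 45, and FCPG library 45 has the lowest trunk Hox score at −5.96.

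Hox genes, which give cells their position along the body axis, were lower in FCPG. The trunk Hox list (paralogue groups 5 to 9) was lower in 15 of 15 members, with a median log2 fold change of −2.45 (camera adjusted p = 8.04e-08). The anterior Hox list (groups 1 to 4) was lower in 11 of 12, with a median of −1.30 (camera adjusted p = 7.97e-06). Both had adjusted p = 0.557 with an estimated correlation, and 0 members of either list passed when adjusted over the list alone, with 7 and 5 members under an unadjusted 0.05. Hoxb7 averaged 11.9 ± 9.45 CPM (SD, n = 3) against 65.4 ± 30.4 CPM (SD, n = 4), and Hoxc9 averaged 5.61 ± 7.60 CPM against 56.7 ± 30.4 CPM. The posterior Hox list (groups 10 to 13) was lower in 9 of 9 members, with a median of −1.52 (camera adjusted p = 0.006). Its adjusted p = 0.622 with an estimated correlation, and its call ended without FCPG library 19 (adjusted p = 0.196) or with an embryo-sex covariate (0.054). The visceral endoderm list moved in the same libraries, and 2 of 3 FCPG and 0 of 4 wild-type libraries were male. With the visceral endoderm score as a covariate the medians were −0.58 (trunk), −0.40 (anterior) and 0.79 (posterior, whose call ended with adjusted p = 0.854), and with the sex covariate the trunk and anterior medians were −1.03 and −1.02. The visceral endoderm score does not overlap between FCPG and wild type, so the fit with it does not settle the source of the Hox change.

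Readouts of FGF signalling went both ways, and their list did not pass. Of 17 members of the FGF-ERK feedback and target list, 10 were lower, with a median log2 fold change of −0.22 (camera adjusted p = 0.0966). With the visceral endoderm score as a covariate the list passed camera as lower (adjusted p = 0.0108, median −0.11). That score does not overlap between FCPG and wild type, so the fit does not tell its effect from that of the group. Dusp6, a phosphatase that is induced by ERK and acts on it, averaged 70.0 ± 11.9 CPM (SD, n = 3) against 121 ± 32.98 CPM (SD, n = 4), with a log2 fold change of −0.79 ± 0.23 (SE). Etv4, a transcription factor induced by FGF, averaged 48.1 ± 31.8 CPM (SD, n = 3) against 108 ± 28.4 CPM (SD, n = 4). Among FGF ligands and receptors, whose list did not pass (camera adjusted p = 0.607), members went both ways. Fgfr3 was 2.61-fold and Fgfr4 5.71-fold higher in FCPG, each higher in 3 of 3 FCPG libraries than in every wild-type library. Klb, a co-receptor for endocrine FGFs, was 19.2-fold higher (log2 4.27 ± 0.82 SE). Fgf17, a tailbud ligand, was at 3.66 ± 3.69 CPM (SD, n = 3) against 36.3 ± 17.3 CPM (SD, n = 4). The visceral endoderm list differed in the same libraries by a median of 3.63.

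Lists of other tissue markers also passed camera. The neural tube list was lower in 18 of 21 members, with a median of −1.26 (camera adjusted p = 3.52e-05). Its adjusted p = 0.557 with an estimated correlation. Irx3, a neural tube transcription factor, averaged 15.9 ± 6.16 CPM (SD, n = 3) against 51.5 ± 23.3 CPM (SD, n = 4). The epiblast and primitive streak list, which marks earlier pluripotent and gastrulating cells, was higher in 16 of 18 members, with a median of 1.37 (camera adjusted p = 0.000349). Its adjusted p = 0.557 with an estimated correlation, and 5 members were higher when adjusted over the list alone. Nanog, a pluripotency factor, averaged 9.39 ± 7.49 CPM (SD, n = 3) against 0.77 ± 0.73 CPM (SD, n = 4). The primitive blood list was lower in 13 of 17 members, with a median of −2.21 (camera adjusted p = 0.00251). Its adjusted p = 0.593 with an estimated correlation, and the call ended without FCPG library 46 (adjusted p = 0.187). Hbb-y, an embryonic globin whose reads can be shared with its near-identical neighbours, was at 0.42 ± 0.73 CPM (SD, n = 3). In wild type it ran from 0.88 CPM in library 33 to 1072 CPM in library 26. With the visceral endoderm score as a covariate the neural tube (adjusted p = 0.999, median 0.06), epiblast (0.999, median 0.06) and blood (0.0554, median −0.35) calls ended, and the epiblast median was 0.62 with the sex covariate. As every FCPG library scored above every wild-type library, the calls ended by that score do not tell tissue content from genotype. Cholesterol synthesis genes were lower in 18 of 20 members, with a median of −0.53 (camera adjusted p = 3.52e-05). Their adjusted p = 0.567 with an estimated correlation; adjusted over the list alone, 7 were lower and 1 higher. Hmgcs1, an early enzyme of the pathway, averaged 99.2 ± 20.3 CPM (SD, n = 3) against 173 ± 41.8 CPM (SD, n = 4).

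In the test of single genes, 0 genes passed edgeR's quasi-likelihood test for FCPG against wild type (smallest adjusted p = 0.104). At an unadjusted p under 0.05 there were 3624 genes, against 829 expected by chance on average. Genes vary together between libraries, and other splits of these libraries gave 146 to 3909 such genes, so the excess does not exclude chance. limma-voom called 0 genes, and DESeq2 called 1461 genes on all 3 groups (1027 higher, 434 lower). The authors' deposited table holds 1200 genes at an adjusted p under 0.05 (767 higher and 433 lower in FCPG). The values of the 2 groups did not overlap in 2411 genes (14.5%), where chance gives 5.71%. Nrarp had a DESeq2 adjusted p = 0.000143 and Lrp2 0.000744. Camera called 26 of 51 lists (7 higher, 19 lower), where other splits of these libraries gave 10 to 34. With an estimated correlation or with the fry test 0 remained. The smallest adjusted p of fry was 0.0585, and it gave 11 lists at an unadjusted p under 0.05. Across the 51 lists, 93 members passed when adjusted over the list alone. Without FCPG library 19, edgeR called 2736 genes, and without wild-type library 33 it called 4; without FCPG library 45, camera called 17 lists.

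The comparison of FCSPG with wild type puts the same question to the other mutant line. Genes of the respiratory chain and of the ribosome were more abundant in FCSPG tailbuds, each by a small margin, and visceral endoderm genes by a larger one. Notch pathway genes and extracellular matrix genes were less abundant. These are calls of lists, each with adjusted p of 0.551 or more with an estimated correlation. Cox8a, a subunit of cytochrome c oxidase, averaged 187.5 ± 40.2 CPM (SD, n = 4) against 122 ± 4.67 CPM (SD, n = 4), a log2 fold change of 0.62 ± 0.16 (SE). Nrarp (ENSMUSG00000078202, chromosome 2, 25070770 to 25073351) averaged 5.39 ± 1.78 CPM (SD, n = 4) against 21.3 ± 8.30 CPM (SD, n = 4), with a log2 fold change of −1.98 ± 0.38 (SE), lower in 4 of 4 libraries than in every wild-type library. As in the other mutant, no gene passed edgeR's test after adjustment, so single genes are given as values.

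Nuclear genes for subunits of the respiratory chain were higher in 75 of 78 members, with a median log2 fold change of 0.37 (camera adjusted p = 1.92e-19). Their adjusted p = 0.551 with an estimated correlation, and 5 were higher when adjusted over the list alone. The median ran from 0.223 to 0.426 with 1 library left out. Cox7c and Uqcr11, subunits of complexes IV and III, were 1.54-fold and 1.56-fold higher, each in 4 of 4 libraries above every wild-type library. Cytosolic ribosomal protein genes were higher in 84 of 87 members, with a median of 0.29 (camera adjusted p = 7.24e-17). Their adjusted p = 0.551 with an estimated correlation, and 0 passed when adjusted over the list alone, with 35 under an unadjusted 0.05. Rpl37 averaged 697 ± 110 CPM (SD, n = 4) against 475 ± 77.0 CPM (SD, n = 4), and Rps28 was 1.58-fold higher. Single ribosomal protein genes are uncertain, because processed pseudogenes of nearly the same sequence can take their reads. Mitochondrial ribosomal protein genes were higher in 72 of 77 members, with a median of 0.24 (camera adjusted p = 1.9e-09) and adjusted p = 0.559 with an estimated correlation. With the visceral endoderm score as a covariate, camera kept the calls of these lists. Their medians were then 0.164 (respiratory chain), 0.249 (cytosolic ribosomal proteins) and 0.126 (mitochondrial ribosomal proteins). Genes of these lists are short, and log2 fold change fell with gene length across all tested genes (Spearman's rho = −0.26 across genes, which are not independent replicates). Random lists matched on length and level had a median of 0.16 against 0.37 for the respiratory chain and 0.16 against 0.29 for the cytosolic ribosomal proteins.

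Notch pathway genes were lower in FCSPG as a list, while FGF readouts went both ways, with a list at the threshold. Spry4, an FGF-induced antagonist of the pathway, averaged 25.5 ± 5.26 CPM (SD, n = 4) against 41.5 ± 3.48 CPM (SD, n = 4). Il17rd, a feedback inhibitor also known as Sef, averaged 74.5 ± 4.42 CPM against 125 ± 28.1 CPM, and both genes were lower in 4 of 4 libraries than in every wild-type library. Dusp4 and Dusp6 were 1.40-fold and 1.57-fold lower. The FGF-ERK feedback and target list was lower in 11 of 17 members with a median of −0.06, just past the threshold (camera adjusted p = 0.0496). Its adjusted p = 0.551 with an estimated correlation, and the call ended without wild-type library 24 (adjusted p = 0.0613) or 33 (0.169), or without FCSPG library 27 (0.0865), 30 (0.153, with a median of 0.03) or 32 (0.0609). The segmentation clock and Notch list was lower in 17 of 19 members, with a median of −0.80 (camera adjusted p = 1.84e-07). Its adjusted p = 0.551 with an estimated correlation, and 3 members were lower when adjusted over the list alone. Notch1 averaged 34.6 ± 10.6 CPM (SD, n = 4) against 75.6 ± 19.3 CPM (SD, n = 4), lower in 4 of 4 libraries. The presomitic mesoderm list was lower in 16 of 20 members, with a median of −0.81 (camera adjusted p = 0.00249). Its adjusted p = 0.551 with an estimated correlation, and the call ended without FCSPG library 30 (adjusted p = 0.109). Tbx6, which commits cells to paraxial mesoderm, averaged 23.0 ± 6.70 CPM (SD, n = 4) against 51.4 ± 5.10 CPM (SD, n = 4), and Dll3 averaged 26.9 ± 7.50 CPM against 67.4 ± 15.7 CPM. Both were lower in 4 of 4 FCSPG libraries than in every wild-type library. Visceral endoderm genes were higher in the same FCSPG libraries, as given below. With their score as a covariate, camera at its preset correlation kept the Notch and presomitic calls as lower. Other differences in tissue content were not separated from these changes.

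**Figure D3:**
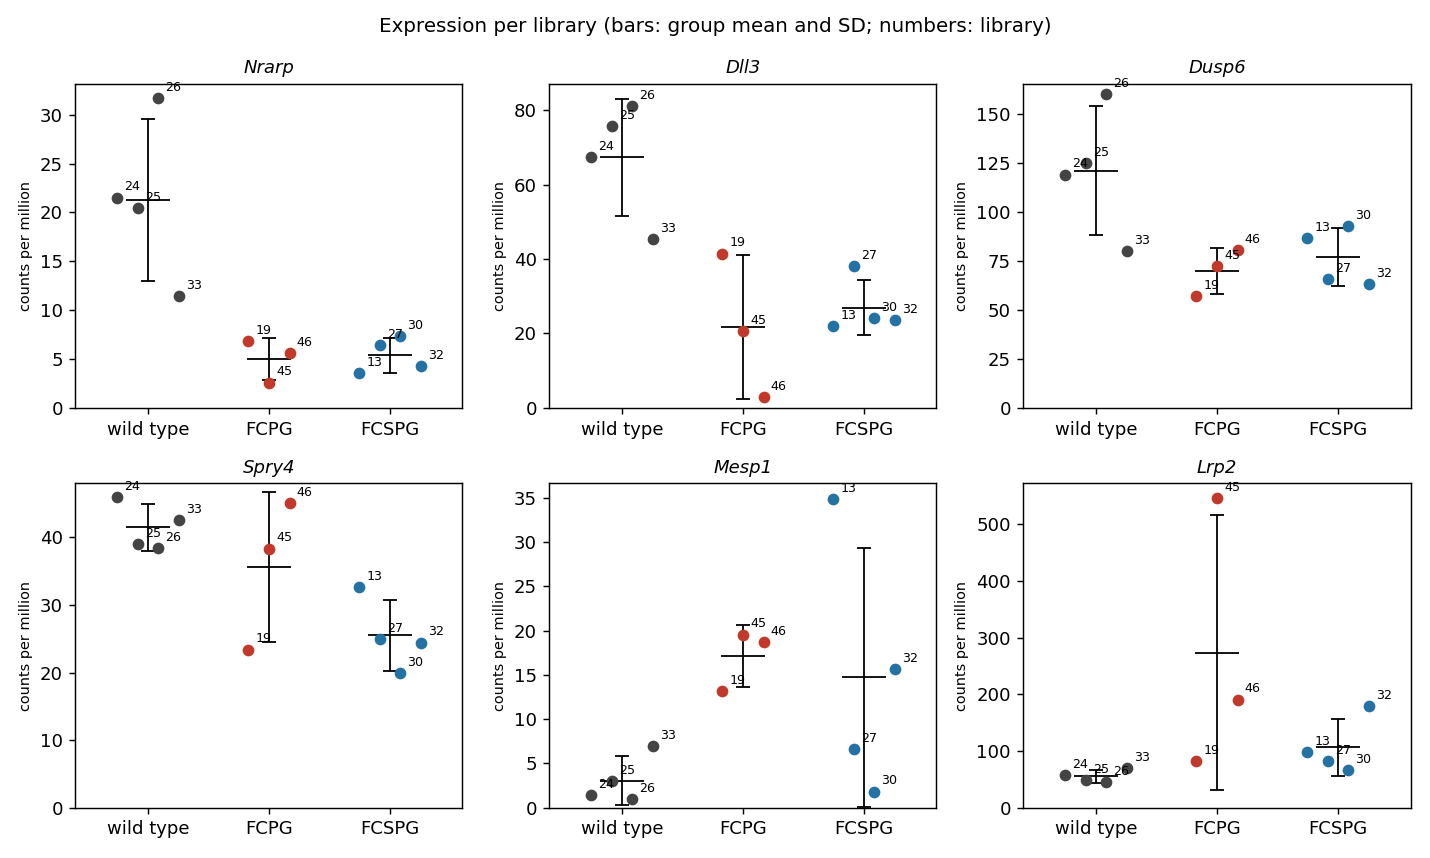
CPM of Nrarp, Dll3, Dusp6, Spry4, Mesp1 and Lrp2 per library in wild type (n = 4), FCPG (n = 3) and FCSPG (n = 4), on linear axes from 0; points are libraries with their numbers, and bars are group means with SD. Nrarp runs from 11.4 to 31.7 CPM in wild type and from 2.599 to 7.314 CPM in the 7 mutant libraries.

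The visceral endoderm list was higher in 20 of 20 members in FCSPG, with a median of 2.17 (camera adjusted p = 7.24e-17). Its adjusted p = 0.551 with an estimated correlation, and 0 members passed when adjusted over the list alone, with 13 under an unadjusted 0.05. Rbp4, the retinol carrier, averaged 299.7 ± 142 CPM (SD, n = 4) against 62.1 ± 47.0 CPM (SD, n = 4). Definitive endoderm genes were higher in 16 of 18 members, with a median of 0.93 (camera adjusted p = 1.84e-07) and adjusted p = 0.551 with an estimated correlation. Cdh1, the epithelial cadherin, was 2.21-fold higher, in 3 of 4 libraries above every wild-type library. The definitive endoderm call ended with the visceral endoderm score as a covariate (adjusted p = 0.149). Basement membrane and matrix genes were lower in 20 of 23 members, with a median of −0.49 (camera adjusted p = 2.86e-06) and adjusted p = 0.551 with an estimated correlation. The list of cadherins and epithelial-mesenchymal transition genes was lower in 18 of 19, with a median of −0.38 (camera adjusted p = 0.000268) and adjusted p = 0.551 with an estimated correlation. Fn1, which encodes fibronectin, averaged 761 ± 66.5 CPM (SD, n = 4) against 1092 ± 193 CPM (SD, n = 4). Pdgfra, a receptor of mesoderm cells, was 1.35-fold lower (log2 −0.44 ± 0.10 SE), in 4 of 4 libraries. Cholesterol synthesis genes were lower in 17 of 20, with a median of −0.49 (camera adjusted p = 2.75e-07) and adjusted p = 0.551 with an estimated correlation.

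Posterior and trunk Hox genes were lower in FCSPG as well, while the anterior Hox list did not pass (camera adjusted p = 0.132). The posterior list was lower in 9 of 9 members, with a median of −1.98 (camera adjusted p = 0.000313), and 2 were lower when adjusted over the list alone. The trunk list was lower in 15 of 15, with a median of −1.05 (camera adjusted p = 9.05e-05). Both had adjusted p = 0.551 with an estimated correlation. Hoxc10 averaged 2.37 ± 1.79 CPM (SD, n = 4) against 62.5 ± 102 CPM (SD, n = 4), where the wild-type SD exceeds its mean. The epiblast and primitive streak list was higher in 14 of 18 members, with a median of 1.02 (camera adjusted p = 0.000268) and adjusted p = 0.551 with an estimated correlation. Nanog averaged 8.47 ± 9.35 CPM (SD, n = 4) against 0.77 ± 0.73 CPM (SD, n = 4). The visceral endoderm list differed in the same libraries by a median of 2.17, and with its score as a covariate the trunk Hox (adjusted p = 0.978), posterior Hox (0.157) and epiblast (0.886) calls ended.

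For FCSPG against wild type, 0 genes passed edgeR's quasi-likelihood test (smallest adjusted p = 0.446). At an unadjusted p under 0.05 there were 1823, against 829 expected by chance on average. Other splits of these libraries gave 59 to 3223 such genes, so the excess does not exclude chance. limma-voom called 0 genes, DESeq2 on all 3 groups 43 (23 higher, 20 lower), and the authors' table holds 482 (331 higher, 151 lower). Nrarp and Notch1 were among the 43, with DESeq2 adjusted p of 0.000572 and 0.0186. The values of the 2 groups did not overlap in 1218 genes (7.35%), where chance gives 2.86%. Camera called 23 of 51 lists (11 higher, 12 lower), where other splits of these libraries gave 7 to 27. With an estimated correlation or with fry 0 remained. The smallest adjusted p of fry was 0.252, with 8 lists at an unadjusted p under 0.05. Across the 51 lists, 16 members passed when adjusted over the list alone. Without wild-type library 33, edgeR called 4 genes.

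The comparison of FCSPG with FCPG asks how the mutant lines differ from each other. Ribosomal protein genes, neural tube genes and anterior Hox genes were more abundant in FCSPG, and visceral endoderm genes less abundant. These are calls of lists, each with adjusted p = 0.59 with an estimated correlation, and the visceral endoderm call ended without FCPG library 45 (adjusted p = 0.422). No gene passed edgeR's test after adjustment, so single genes are given as values. Rps2, a protein of the small ribosomal subunit, averaged 2966 ± 318 CPM (SD, n = 4) in FCSPG against 2184 ± 336 CPM (SD, n = 3) in FCPG, a log2 fold change of 0.44 ± 0.13 (SE). Irx3 averaged 42.1 ± 23.0 CPM (SD, n = 4) against 15.9 ± 6.16 CPM (SD, n = 3), with a log2 fold change of 1.40 ± 0.51 (SE).

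The cytosolic ribosomal protein list was higher in FCSPG in 83 of 87 members, with a median log2 fold change of 0.42 (camera adjusted p = 9.25e-29). Its adjusted p = 0.59 with an estimated correlation, and 60 members were higher when adjusted over the list alone. Random lists matched on length and level had a median of 0.23, so part of the difference is shared by genes of that kind. With the gene-length trend removed the list's median was 0.29 and camera kept the call (adjusted p = 1.91e-20). The mutants lay on opposite sides of wild type: the median was 0.29 in FCSPG and −0.11 in FCPG, where 72 of 87 members were lower (camera adjusted p = 0.0183, and adjusted p = 0.904 with an estimated correlation). That FCPG call ended without wild-type library 24 (adjusted p = 0.0653), 25 (0.212) or 33 (0.0718), and without FCPG library 45 (0.52) or 46 (0.291). Matched random lists had a median of −0.07 in FCPG against wild type, beside −0.11 for the list. The mitochondrial ribosomal protein list was higher in 69 of 77 members, with a median of 0.19 (camera adjusted p = 2.92e-06) and adjusted p = 0.59 with an estimated correlation. The respiratory chain list was higher in 67 of 78, with a median of 0.23 (camera adjusted p = 3.17e-06) and adjusted p = 0.601 with an estimated correlation. Its call ended without FCPG library 46 (adjusted p = 0.0544) and with the gene-length trend removed (adjusted p = 0.0992, median 0.07), and random lists matched on length and level had a median of 0.21. Rps20 was 1.52-fold and Rps9 1.39-fold higher, both with reads that pseudogene copies can share.

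Neural tube genes were higher in FCSPG in 20 of 21 members, with a median of 1.17 (camera adjusted p = 1.89e-06), and anterior Hox genes in 12 of 12, with a median of 0.78 (camera adjusted p = 1.53e-05). Both had adjusted p = 0.59 with an estimated correlation, and 0 members of either passed when adjusted over the list alone, with 1 in each under an unadjusted 0.05. The neural tube median ran from 0.75 without FCSPG library 30 to 2.48 without FCPG library 19, and the anterior Hox median from 0.39 without FCPG library 45 to 1.85 without FCPG library 19. Hoxb4 was 2.06-fold higher (log2 1.05 ± 0.45 SE). Retinoic acid pathway genes were higher in 15 of 18 members, with a median of 0.65 (camera adjusted p = 0.00142) and adjusted p = 0.59 with an estimated correlation. Targets of p53 were higher in 15 of 19 members, with a median of 0.28 (camera adjusted p = 0.00501). Their adjusted p = 0.412 with an estimated correlation, the smallest of the 51 lists. Bbc3, a p53-induced death gene, was 1.81-fold higher (log2 0.86 ± 0.31 SE). The neuromesodermal progenitor list, which marks the shared source of spinal cord and somites, was higher in 15 of 16 members, with a median of 0.60 (camera adjusted p = 0.00036). Its adjusted p = 0.59 with an estimated correlation, and the call ended without FCPG library 45 (adjusted p = 0.207). Nog, which encodes the BMP antagonist noggin, averaged 12.3 ± 4.27 CPM (SD, n = 4) against 5.47 ± 2.26 CPM (SD, n = 3). Wnt4 averaged 20.3 ± 6.4 CPM against 8.15 ± 4.10 CPM, and both genes were higher in 4 of 4 FCSPG libraries than in every FCPG library.

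The visceral endoderm list was lower in FCSPG than in FCPG in 20 of 20 members, with a median of −1.41 (camera adjusted p = 0.000158) and adjusted p = 0.59 with an estimated correlation. The trunk Hox list was higher in 14 of 15, with a median of 1.27 (camera adjusted p = 0.00036) and adjusted p = 0.59 with an estimated correlation. Both calls ended without FCPG library 45, with adjusted p = 0.422 for the visceral endoderm list and 0.459 for the trunk Hox list. The trunk Hox call also ended with an embryo-sex covariate (adjusted p = 0.173, median 0.28), where 2 of 3 FCPG and 1 of 4 FCSPG libraries were male. The FGF-ERK list did not pass between the mutants, with 9 of 17 members higher and a median of 0.04 (camera adjusted p = 0.861). Spry4 averaged 25.5 ± 5.26 CPM (SD, n = 4) in FCSPG against 35.6 ± 11.1 CPM (SD, n = 3) in FCPG. Fgf8, a ligand of the tailbud, averaged 51.1 ± 15.6 CPM against 24.03 ± 16.5 CPM.

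For FCSPG against FCPG, 0 genes passed edgeR's quasi-likelihood test (smallest adjusted p = 0.435). At an unadjusted p under 0.05 there were 1897, against 829 expected by chance on average. Other splits of these libraries gave 198 to 4423 such genes, so the excess does not exclude chance. limma-voom called 0 genes, DESeq2 1 gene, and the authors' table holds 0 at an adjusted p under 0.05. The 1 gene was Pcna-ps2, named after its value was seen, a processed pseudogene of Pcna whose reads cannot be told from those of its parent (log2 0.80, DESeq2 adjusted p = 0.00912). The values of the 2 groups did not overlap in 774 genes (4.67%), where chance gives 5.71%. Camera called 25 of 51 lists (20 higher, 5 lower), where other splits of these libraries gave 12 to 28. With an estimated correlation or with fry 0 remained. The smallest adjusted p of fry was 0.192, with 4 lists at an unadjusted p under 0.05. Across the 51 lists, 62 members passed when adjusted over the list alone. Without FCPG library 19, edgeR called 1063 genes, and without FCPG library 45, camera called 15 lists.

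The mutants were also compared with each other through their differences from wild type. The log2 fold changes of FCPG and FCSPG against wild type had a Pearson correlation of 0.782 across the 16572 genes, which are not independent replicates. Both comparisons share the 4 wild-type libraries, and simulated unchanged groups against those libraries gave a mean correlation of 0.454 (20 simulations). The covariance was 0.435, against 0.0907 in the simulations. With the wild-type libraries split into pairs, over 6 splits, the mean correlation was 0.601 (0.504 to 0.661) and the mean covariance 0.385. The fold changes had the same sign in 69.8% of genes, against 65.2% in the simulations. Without FCPG library 19 the correlation was 0.614 and the same sign held in 64.3% of genes, and without FCSPG library 32 these were 0.667 and 65.2%. With edgeR, 0 genes passed in both mutants, since 0 passed in either, where 3624 and 1823 genes lay under an unadjusted 0.05. With DESeq2, 33 genes passed in both in the same direction, 18 higher and 15 lower, where independent lists would share 1.31 and 0.48 genes. In 5 simulations of unchanged groups with DESeq2, 0 to 4 genes were shared. With DESeq2 on the 2 groups of each comparison, 259 genes passed in both, 207 higher and 52 lower, where independent lists would share 13.8 and 3.48 genes and the simulations shared 1 to 4. All these simulations drew genes independently of each other, whereas component 1 held 46.9% of the variance in the real libraries. They therefore do not show how much correlation or overlap such shared variation between libraries gives without a genotype effect. Nrarp was lower in 7 of 7 mutant libraries than in every wild-type library. Dll3 was at 67.4 ± 15.7 CPM in wild type (SD, n = 4), 21.7 ± 19.3 CPM in FCPG (SD, n = 3) and 26.9 ± 7.50 CPM in FCSPG (SD, n = 4).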

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

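The comparison of visceral endoderm with neural tube genes, the test of a swap of libraries, the position of library 19 without library 33 and the fits with sex, with the visceral endoderm score or with the gene-length trend removed were chosen after results were seen. Predictions for the other tests were written before those tests were run. The tests of visceral endoderm genes, of ribosomal and respiratory chain genes and of library 19 address patterns already seen in the results. The splits with DESeq2 on 2 groups use a fit that was added after the data were seen.

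Visceral endoderm genes were higher in both mutants, in 20 of 20 members each, with median log2 fold changes of 3.63 in FCPG and 2.17 in FCSPG. The tables argue against embryo sex as the whole cause, since the FCPG median was 2.91 with a sex covariate (camera adjusted p = 3.47e-19), while the list without that covariate had adjusted p = 0.557 with an estimated correlation. They argue against a smaller share of mesoderm cells only where that would raise markers of all other tissues alike. The visceral endoderm median exceeded that of the neural tube by 4.88 (95% bootstrap intervals 3.50 to 3.79 and −1.72 to −0.78). Surface ectoderm and definitive endoderm had medians of 0.21 and 1.20. The intervals resample genes and do not measure the spread between libraries. Spinal cord and somites share a source, so a loss of that source could lower both and stays open. Carried-over visceral endoderm may be the source, since 1 factor per library held 95% of the list's variance against a median of 52.5% in random lists; 9 of 20 members were over 1 CPM in every wild-type library, 0 are in another list, and Apoe, the most abundant, averaged 139, 2120 and 802 CPM in wild type, FCPG and FCSPG. More visceral endoderm in the mutant embryos themselves would give the same value and stays open, as does the genotype's effect on these genes, which was not tested apart from tissue content.

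Ribosomal protein and respiratory chain genes were higher in FCSPG than in wild type, with medians of 0.29 and 0.37 and adjusted p = 0.551 for both lists with an estimated correlation. Gene length is not the whole cause: with the length trend removed, the medians were 0.19 and 0.26 and the ribosomal list kept its call (adjusted p = 1.73e-10). No single library accounts for the direction: with 1 left out, the medians ran from 0.194 to 0.335 (ribosomal) and from 0.223 to 0.426 (respiratory chain). Their size did depend on the libraries. The highest camera adjusted p of either list was then 2.51e-11. With all libraries these values were 7.24e-17 and 1.92e-19 at the preset correlation, so 1 library could hardly have ended a call. Reads shared with pseudogenes and unequal RNA quality were not tested and stay open, as does a difference that follows the genotype.

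No gene passed in FCPG against wild type with all libraries, and 2736 passed without FCPG library 19. Unequal visceral endoderm content stays open: 0 genes passed with that score as a covariate, but the limit set in advance was wrong. The lowest FCPG score of 5.46 exceeds the highest wild-type score of 4.99, so the fit extends the trend within groups across a gap. A mislabelled wild-type library stays open: from the wild-type mean at 0 to the mean of FCPG libraries 45 and 46 at 1, library 19 lay at 0.311, inside the wild-type range of −0.12 to 0.353, but without library 33, the upper end, it lay at 0.408 against −0.015 to 0.102. It lay outside the wild-type range in 34 of 51 lists, where chance gives 40%, on the side of the other FCPG libraries in 15 and on the opposite side in 19, with a trunk Hox score of 3.45 against 4.88 to 6.13, so a mutant with a weaker effect stays open too. A swap of wild-type library 33 with FCSPG library 30 also stays open: the presomitic mesoderm score of library 33 exceeded that of library 30 by 0.786 (group SDs 0.127 and 0.182), against a swap, but from the other wild-type libraries at 0 to the other FCSPG libraries at 1 over all genes, libraries 33 and 30 lay at 0.635 and 0.284, the order a swap would give, as in 34 of 51 lists.

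Other results stood apart and are given as values. The endothelium score of wild-type library 33 was 4.03, against 4.60 to 4.72 in the other wild-type libraries. The hypoxia score of FCSPG library 30 was 5.93, against 5.41 to 5.43 in the other FCSPG libraries. These 2 came from 104 tests for a library far from its group, of which chance gives about 5.2. The cytosolic ribosomal protein list went opposite ways in the mutants against wild type, and their difference passed camera (adjusted p = 9.25e-29, and adjusted p = 0.59 with an estimated correlation). Its FCPG call ended with a sex covariate (adjusted p = 0.0789) and was kept in 2 of 7 fits with 1 library left out. Random lists matched on length and level had a median of 0.23 between the mutants, against 0.42 for this list. Y-linked genes, which no comparison used, were at 170 and 183 CPM in FCPG libraries 19 and 45 and 180 CPM in FCSPG library 32, against 0 CPM in the wild-type libraries.

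Splits of the same libraries into groups of the same sizes were tested against each result, and each count of splits below includes the real one. Since edgeR called 0 genes in each real split, every one of the 35 splits gave as many, so genes at an unadjusted p under 0.05 were counted instead. For FCPG against wild type, 3 of 35 splits gave as many as the real 3624. The highest other, 3909, had wild-type library 33 in place of FCPG library 19. The next, 3644, set wild-type libraries 24, 25 and 26 apart from the rest. An exchange of libraries 33 and 19 was not tested further and stays open. For FCSPG against wild type, 2 of 35 splits gave as many as 1823, the highest other being 3223. For FCSPG against FCPG, 8 of 35 splits gave as many as 1897, the highest other being 4423. For lists past camera's threshold, 7 of 35 splits gave as many as 26 in FCPG (highest other 34). In FCSPG 2 of 35 gave as many as 23 (highest other 27), and between the mutants 10 of 35 as many as 25 (highest other 28). The lowest counts were 10, 7 and 12 lists, so camera at its preset correlation called lists in every split. With DESeq2 on the tested genes of the 2 groups, 2 of 35 splits gave as many as 1163 in FCPG (highest other 1410) and 3 of 35 as many as 477 in FCSPG (highest other 2713). The 1410 came from wild-type libraries 24, 25 and 26 against the rest, and library 33 in place of 19 gave 1082. Chance is therefore not excluded for any of these counts. The split of wild-type libraries 24, 25 and 26 with FCSPG library 30 from the rest gave the 2713, several times the real count. That points to a structure of the samples other than the groups. It is the split that a swap of libraries 30 and 33 would make. It is also the order of the visceral endoderm score. The highest score on the side of library 30 was its own 4.64, and the lowest on the other side was 4.99 in library 33. The split therefore does not tell a swap from unequal visceral endoderm content.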

How the results depend on the processing

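The fits with an embryo-sex covariate, with the visceral endoderm score, without the male libraries and with the gene-length trend removed, DESeq2 on 2 groups, the permutation of list scores and DESeq2's shared genes were chosen after the data were seen. No paired analysis was possible because the column names carry no replicate numbers that match the sample titles. Where no cause is given for a change, the cause was not tested. In simulations at the real depth, 27%, 45% and 35% of genes changed 2-fold were recovered with the fitted dispersions. With a dispersion of 0.01 these were 96%, 99% and 96%, so in the simulations the spread limits recovery more than depth does. They drew genes independently of each other, so these shares need not hold in the real libraries. Why 0 genes passed in the real data was not tested.

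Genes called stayed at 0 in all 3 comparisons with DESeq2 size factors, a filter of 1 CPM, limma-voom, only the 2 groups compared, the length trend removed, either covariate and a minimum log2 fold change of 1. In FCPG against wild type they were 403 with no filter, 1461 with DESeq2, 1200 with DESeq2 on 2 groups, 144 without the male libraries, which leaves FCPG library 46 alone in its group, and from 0 to 2736 with 1 library left out, the highest without FCPG library 19, with 4 without wild-type library 33. Of the 2736 genes, 1192 were among DESeq2's 1461, and of the 2701 in the main test 1949 had the same direction in library 19. In FCSPG against wild type they were 43 with DESeq2, 457 with DESeq2 on 2 groups and from 0 to 4 with 1 library left out, the highest without wild-type library 33. Between the mutants they were 1 with DESeq2, 28 without the male libraries, again with 1 FCPG library, and from 0 to 1063 with 1 library left out, the highest without FCPG library 19. Genes changed in both mutants were 33 with DESeq2, 259 with DESeq2 on 2 groups (207 higher, 52 lower) and from 0 to 3 with 1 library left out, the highest without wild-type library 33. The correlation of fold changes was from 0.614 to 0.847 with 1 library left out, lowest without FCPG library 19 and 0.667 without FCSPG library 32, and 0.601 with split wild-type libraries.

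Lists called were 0 in all 3 comparisons with an estimated correlation, with fry and with the exact permutation of scores, whose smallest adjusted p was 0.208, 0.243 and 0.546. That permutation cannot give a p under 0.0286, so after adjustment over 51 lists a call needed many lists at this floor. At an unadjusted permutation p under 0.05 there were 7, 4 and 1 lists. In FCPG they were 13 with the visceral endoderm score and from 17 to 25 with 1 library left out, lowest without FCPG library 45. In FCSPG they were from 16 to 20, lowest without FCSPG library 30, and between the mutants from 15 to 30, lowest without FCPG library 45. Left-out libraries moved the median over 1.5-fold in 22 of 26, 12 of 23 and 24 of 25 calls. The visceral endoderm score as a covariate did so in 25, 16 and 7 of these calls, and the sex covariate in 9, 6 and 7. Calls kept whichever library was left out were 9 of 26 in FCPG, 15 of 23 in FCSPG and 7 of 25 between the mutants. With the visceral endoderm score as a covariate 10, 15 and 21 calls were kept, and with the sex covariate 18, 23 and 21. The visceral endoderm score was higher in every FCPG library than in every wild-type library, so in FCPG the fit does not tell its effect from that of the group. Among the FCPG calls it ended were neural tube (adjusted p = 0.999), epiblast (0.999), definitive endoderm (0.999), posterior Hox (0.854), Wnt ligands (0.413), somite (0.346) and primitive blood (0.0554). Among the FCSPG calls it ended were trunk Hox (0.978), posterior Hox (0.157) and definitive endoderm (0.149). Among the calls that the sex covariate ended were posterior Hox (0.054), cytosolic ribosomal proteins (0.0789), endocytosis (0.0584), neural crest (0.228) and respiratory chain (0.447) in FCPG and trunk Hox (0.173) between the mutants. With the gene-length trend removed 26, 20 and 20 calls were kept, and the respiratory chain (0.0992) and matrix (0.0625) calls between the mutants ended.

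Some lists turned direction, given with their adjusted p. In FCPG against wild type with the visceral endoderm score these were visceral endoderm (0.999), trophoblast (0.999), respiratory chain (0.00302) and mitochondrial ribosomal proteins (0.00209); for the visceral endoderm list the covariate is its own score. Without the male libraries, with FCPG library 46 against 4 wild-type libraries, they were PDGF and other receptor kinases (0.016), allantois (7.22e-05), posterior Hox (0.599), respiratory chain (0.159), mitochondrial ribosomal proteins (0.0101) and imprinted genes (0.00178), and with the sex covariate allantois (0.0475). In FCSPG against wild type with the visceral endoderm score these were somite (0.0479), primitive blood (0.666), visceral endoderm (0.886), neural tube (2.37e-08), neural crest (0.0453), epiblast (0.886), Wnt ligands (0.00588), BMP (0.886) and anterior Hox (0.043). Between the mutants, without the male libraries and so with 1 FCPG library, these were definitive endoderm (0.0213), germ cell (5.49e-06), posterior Hox (0.000454) and hypoxia (0.724). With 1 library left out, the adjusted p ranged from 0.000336 to 0.985 for allantois, from 0.00393 to 0.771 for cadherins and from 0.000857 to 0.995 for endocytosis.

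Fgfr1, which passed no test, had log2 fold changes near 0 that turned. In FCPG against wild type its value was −0.187 with the sex covariate, −0.0815 without the male libraries (FCPG library 46 alone) and from −0.0981 to 0.139 with 1 library left out. In FCSPG it was 0.0307 with the visceral endoderm score and from −0.18 to 0.0563 with 1 left out, and between the mutants 0.0608 with the sex covariate and from −0.237 to 0.0884 with 1 left out.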

Other observations

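The test of embryo stage and the fit with the visceral endoderm score were chosen after the result was seen, as were the genes named with a library left out; the list tests were chosen before.

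Genes of endocytosis and vesicle trafficking, through which receptors are taken up and recycled, were higher in FCPG in 22 of 32 members, with a median log2 fold change of 0.20 (camera adjusted p = 0.0245). Their adjusted p = 0.65 with an estimated correlation, and the call ended without wild-type library 25 (adjusted p = 0.0548) or 33 (0.0686) or FCPG library 45 (0.525). Adjusted over the list alone, 4 members were higher. Eea1, an early endosome tether, averaged 70.3 ± 45.4 CPM (SD, n = 3) in FCPG against 25.4 ± 5.93 CPM (SD, n = 4) in wild type, and Lamp1, a lysosomal membrane protein, was 2.00-fold higher. Rab4a, a GTPase of fast recycling, was 2.53-fold higher in FCPG and 1.82-fold higher in FCSPG, above every wild-type library in 3 of 3 and 4 of 4 libraries. The list did not pass in FCSPG, with 17 of 32 members higher (camera adjusted p = 0.768). Visceral endoderm takes up material by endocytosis, and its list differed in the same libraries by a median of 3.63 in FCPG. With its score as a covariate the endocytosis call ended (adjusted p = 0.597), but that score does not overlap between FCPG and wild type. Genes for adaptors and effectors that bind FGFR1 did not pass as a list in FCPG (camera adjusted p = 0.607), in FCSPG (0.398) or between the mutants (0.0812). Grb14, an adaptor of receptor tyrosine kinases, averaged 5.11 ± 1.99 CPM (SD, n = 3) in FCPG and 4.52 ± 1.05 CPM (SD, n = 4) in FCSPG against 2.71 ± 0.27 CPM (SD, n = 4), above every wild-type library in all 7 mutant libraries.

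Genes of BMP and TGF-beta signalling were higher in FCPG in 21 of 27 members, with a median of 0.51 (camera adjusted p = 0.0204). Their adjusted p = 0.593 with an estimated correlation, and the call ended without FCPG library 46 (adjusted p = 0.797) or with the visceral endoderm score as a covariate (adjusted p = 0.999, median 0.20). Adjusted over the list alone, 6 members were higher and 1 lower, and Bmp2 and Bmp7 were 2.14-fold and 1.98-fold higher. Wnt ligand and planar polarity genes were lower in FCPG in 18 of 24 members, with a median of −0.42 (camera adjusted p = 0.0023). Their adjusted p = 0.557 with an estimated correlation, and the call ended without FCPG library 45 (adjusted p = 0.113) or with the visceral endoderm score (adjusted p = 0.413, median −0.06). That score does not overlap between FCPG and wild type, so neither the BMP nor the Wnt call lost with it shows a cause. The Wnt ligand list did not pass in FCSPG (camera adjusted p = 0.712). Wnt5a, which guides cell movement and outgrowth of the tail, averaged 104 ± 7.27 CPM (SD, n = 4) in FCSPG against 178 ± 41.8 CPM (SD, n = 4), lower in 4 of 4 libraries. Surface ectoderm genes were higher in FCSPG in 12 of 14 members, with a median of 0.61 (camera adjusted p = 0.000789) and adjusted p = 0.551 with an estimated correlation. Epcam and Cldn7, epithelial genes that endoderm also expresses, were 1.57-fold and 2.00-fold higher. Mitosis genes were lower in FCSPG in 14 of 22 members, with a median of −0.09 (camera adjusted p = 0.023), and 2 were lower when adjusted over the list alone. Their adjusted p = 0.551 with an estimated correlation, and the call ended without wild-type library 33 (adjusted p = 0.158) or FCSPG library 27 (0.0535) or 30 (0.202). Mki67, the proliferation marker, averaged 372 ± 26.4 CPM (SD, n = 4) against 471 ± 51.0 CPM (SD, n = 4), lower in 4 of 4 libraries.

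Without wild-type library 33, 4 genes passed edgeR's test in FCPG, all lower: Gm11249, Gm5805, Gm7931 and Gm10182. In FCSPG the 4 were Gm11249, Gm7931, Gm10182 and Tg, which encodes thyroglobulin, so 3 genes were shared by comparisons that use the same 3 remaining wild-type libraries. The log2 fold change of Gm7931 was −2.29 in FCPG (adjusted p = 0.00399) and −2.04 in FCSPG (adjusted p = 0.00411). These genes were named after their values were seen. The Gm genes are predicted genes, some of them pseudogenes that can share reads with a parent gene, so their levels are uncertain.

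A hypothesis of an earlier developmental stage in the mutant embryos was set up after the pattern was seen. The trunk Hox, posterior Hox, somite and primitive blood lists passed camera as lower and the epiblast list as higher in both mutants, with adjusted p of 0.551 or more with an estimated correlation. The anterior Hox list did not pass in FCSPG (camera adjusted p = 0.132). In FCSPG the somite list (camera adjusted p = 0.023) and the blood list (0.0149) had adjusted p = 0.7 and 0.604 with an estimated correlation. The somite call ended without wild-type library 25 (adjusted p = 0.0606) or FCSPG library 13 (0.138) or 32 (0.118), and the blood call without wild-type library 26 (0.157) or FCSPG library 30 (0.0554). With the visceral endoderm score as a covariate in FCSPG, the somite list turned higher (adjusted p = 0.0479, median 0.59), the blood list turned higher without passing (0.666), and the trunk Hox (0.978), posterior Hox (0.157) and epiblast (0.886) calls ended. Wild-type library 33 lay beyond the other 3 wild-type libraries on the side of the mutants in 4 of 5 such lists, the posterior Hox list being the exception. That library was picked because it lies nearest to the mutants, and the lists because they differ in the mutants, so the value decides nothing about stage. The labels give 1 embryonic day for all libraries, and stage and genotype were not separated. The presomitic mesoderm score of library 33 lay inside the range of the other wild-type libraries. FCSPG library 30, whose epiblast score was −0.03 from the wild-type mean, had a presomitic score of −0.82 and a Tbx6 level of 15.6 CPM, under the 47.2 CPM of the lowest wild-type library.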
